A study of Gallus gallus with 8 samples.

How the data were processed

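Gene expression was measured with Affymetrix chicken arrays in sensory epithelia of the chick inner ear, 4 from the utricle and 4 from the cochlea, 1 array each. The labels call the 4 arrays of a tissue biological replicates. Embryos grew at 38 °C to day 20 or 21, and the epithelia were microdissected to hold hair cells and supporting cells. Total RNA came from 10 to 20 pooled epithelia per sample, and labelling used 0.08 μg of it. The authors made the deposited values as log2 GCRMA signal, by GC-content based background correction, quantile normalization across arrays and median polish over the probes of a probe set, per the notes in their workbook. No version of GCRMA was stated. The deposited workbook also gives the authors' SAM comparison of the tissues, with the fold difference as a ratio in the called direction and the q-value in percent. The value table and the workbook held the same values for each tissue. A further 136 columns of the workbook with values or detection calls per array were not used.

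Each array carried 38535 probe sets, of which 96 were controls and were left out. The deposited sheet names no gene for 14193 of them. A table of RefSeq genes on the assembly GRCg7b served for names only, through gene numbers, accessions and symbols, and named 17671 probe sets of 10426 genes. A further 123 probe sets of 90 genes, all members of the gene lists below, were named by hand from the sheet's descriptions, among them CRABP1, SEMA3D, BMP7, CHRNA7, THBS2, HAPLN1, SPP1, GJA1, RPS13, CHRDL1 and KCNMA1. The remaining named probe sets kept the sheet's own name or number. No coordinates were used.

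The following choices were made before the data were examined. Probe sets with a log2 signal above 4 on at least 4 of the 8 arrays were tested. The tissues were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, utricle minus cochlea, two-sided), and p-values were adjusted by the method of Benjamini and Hochberg over all probe sets tested. Calls were made at an adjusted p under 0.05, and counted again with at least a 2-fold difference. A second test at the level of genes used the tested probe set with the highest mean signal over all arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Ranges given with a difference are 95% confidence intervals of the limma fit, and errors given with a mean are SDs over 4 arrays.

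There were 31 gene lists. Of these, 21 concerned the biology of the ear epithelia (hair cells, supporting cells, stereocilia and mechanotransduction, tectorial and otolithic membranes, potassium and calcium channels, synapses, otic transcription factors, the Notch, Wnt, BMP and TGF-beta, FGF, hedgehog, retinoic acid and angiogenesis pathways, axon guidance, gap junctions, the cell cycle, motile cilia, immediate early and heat shock genes, cytosolic ribosomal proteins and oxidative phosphorylation). The other 10 held markers of cell types that a dissected epithelium could carry along, and the result of 1 of them is not reported here. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01. An estimated correlation and the rotation test fry were alternatives. Gene counts for each list are also given adjusted over the list alone.

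Genes are named by a rule with 3 parts. The first takes the 12 genes with the largest difference in each direction among those past the threshold, with no overlap of the tissues, a mean of at least 6 in the brighter tissue and a proper symbol. The second takes from each list up to 2 members per direction with the smallest adjusted p. The third names 22 genes in any case. Where the mean of the dimmer tissue, or any of its arrays, was under 4, the fold is a lower bound, written "at least", with array values under 4 raised to 4. That bound, the way names were assigned and the medians with dim means raised were set after the data were seen.

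The replicate numbers are shared by the tissues. Deviations from the tissue means, across the tested probe sets, correlated at 0.552, 0.48, 0.404 and 0.144 for the arrays numbered 1 to 4. Each was above 0.1, so the numbers were taken to pair the samples before the calls of the paired fit were read. The pairing comes from the data, since the labels do not say what a number stands for, and cochlea array 4 correlated more with utricle array 3 (0.304) than with utricle array 4. In the array names of the workbook, 1 utricle number has no equal among the cochlea numbers. By their values, the arrays numbered 1 were those under the smaller prefix of the array names. Their correlation cannot be told apart from an effect of that prefix.

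Alternatives fixed in advance were the workbook values, no filter, a filter at 6, the probe sets that the authors list as detected, quantile normalization, an equal median per array, eBayes with trend and robust, array weights, a SAM-style statistic with a false discovery rate from the 35 distinct splits of the arrays, the replicate number as a block, the mean over a gene's probe sets, and leaving out each array in turn. Added after the data were seen were a block for the prefix of the array names, a fit within the 6 arrays of the larger prefix, a fit without the arrays numbered 2 and a fit without the 2 utricle arrays with high CALB1.

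The fit was tested on simulated data, in which 200 of 16223 probe sets were changed. It recovered 28.4% of those changed by 0.5 on the log2 scale, 70.1% of those changed by 1 and 100% of those changed by 2, and 5.71% of its calls were false. The block recovered 0%, 41.8% and 93.9%, and the SAM-style test 10.4%, 67.2% and 100%. The simulated noise was independent between arrays and lacked the shared deviations of equally numbered arrays. These shares therefore do not show how the block performs on the real arrays. With the hair cell list shifted by 0.5 on the log2 scale, camera gave it an adjusted p of 2.59e-27, or 4.68e-04 with an estimated correlation. It called 1 other list, stereocilia and mechanotransduction, which shares members. The simulated genes were uncorrelated, while the real hair cell list had an estimated correlation of 0.283. The simulated result therefore does not show the power of camera on the real arrays.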

Results

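The samples were sensory epithelia of the chick inner ear at embryonic day 20 to 21, from the cochlea, the hearing organ, and from the utricle, a balance organ. There were 4 arrays of each tissue, each with RNA from 10 to 20 pooled epithelia. Between 40.97% and 41.76% of the 38535 probe sets on an array had a log2 signal above 4. Across probe sets, which are not independent replicates, arrays correlated at 0.9929 to 0.996 within the utricle, 0.9945 to 0.9971 within the cochlea and 0.9622 to 0.9697 between the tissues. The number of arrays limits the precision.

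The comparison asked which genes differ in expression between the utricular and the cochlear epithelium. Among the genes higher in the utricle, CRABP1, which binds retinoic acid inside cells, was at least 219-fold higher, at 11.77 ± 0.22 against 2.34 ± 0.15 (mean log2 signal ± SD, n = 4 arrays per tissue, here and below). OTOL1, the otolith protein otolin, was 308-fold higher, at 14.20 ± 0.15 against 5.93 ± 1.01. PLXNA4, a semaphorin receptor, was 365-fold higher, and RSPO3, a secreted activator of Wnt signalling, was 276-fold higher. In the cochlea, the calcium buffer CALB1 reached 15.37 ± 0.035 against 4.84 ± 2.72 in the utricle and was at least 879-fold higher, or at least 609-fold without utricle array 1 or 4 and at least 1357-fold without array 2. Of the 4 utricle arrays, 2 were under 4 and the other 2 far above. NEFM, the medium neurofilament protein, was at least 455-fold higher in the cochlea, GSTTL at least 665-fold and the phosphate transporter SLC34A2 at least 424-fold. The nuclear receptor NR2F2 was 279-fold higher in the cochlea, at 14.15 ± 0.14 against 6.03 ± 1.36, and RORB was at least 49.6-fold higher.

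The other genes among the 12 largest differences toward the utricle were RASD2, ST8SIA6, ADH6, NMB, ADCY8, AMIGO2, VCAN and CIB3. Toward the cochlea they were SOX7, CRISP3, CA4, DCLK3, SEMA3D and PLA2G10. Where a tissue had values under 4, the fitted difference by which these genes were picked rests on background signal, so neither the choice nor the order of the 12 is firm. At an adjusted p under 0.05, limma called 4286 of 16223 tested probe sets higher in the utricle and 4066 higher in the cochlea. With at least a 2-fold difference, the counts were 1811 and 1630. Of 8514 genes, 2320 were higher in the utricle and 2311 in the cochlea, so 50.1% of the 4631 called genes were higher in the utricle. The tissues did not overlap in 4342 of the 8514 tested genes, called or not, where chance alone separates the tissues in 2.86% of genes. The array names carried 2 prefixes, with 1 array of each tissue under the smaller. Under the larger, the number after the prefix set 1 utricle array apart from the other arrays. Within the 6 arrays of the larger prefix, 1954 genes were higher in the utricle and 1972 in the cochlea, and with the prefix as a block 2405 and 2385 were. Under the smaller prefix, with 1 array per tissue and no test, 87.7% of the 8514 tested genes differed in the same direction as under the larger.

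**Figure D1:**
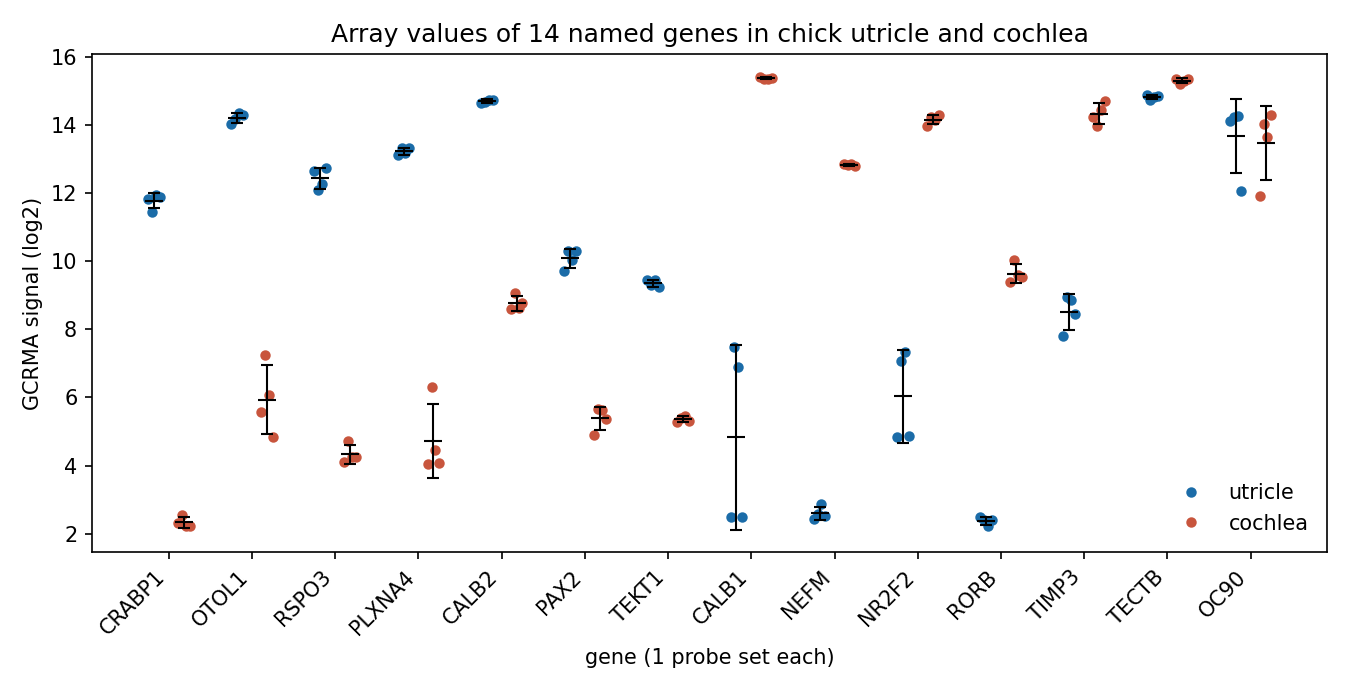
Log2 GCRMA signal of 14 named genes on each array (points), with the mean and SD of the 4 arrays of each tissue (bars), utricle in blue and cochlea in red. CALB1 lies at 15.37 in the cochlea and is spread over the utricle arrays with an SD of 2.72, while OC90 has 1 lower array in each tissue.

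Hair cell genes differed in both directions. CALB2, the calcium buffer calretinin, was 61.0-fold higher in the utricle (14.70 ± 0.048 against 8.77 ± 0.22, log2 difference 5.93, 95% interval 5.67 to 6.19), and USH1C, the scaffold protein harmonin, 5.74-fold higher. MYO3A, a myosin of stereocilia, was 11.9-fold higher in the cochlea and CIB2 5.02-fold. Of 26 tested hair cell genes, 9 were higher in the utricle, 10 in the cochlea and 7 did not pass, and the counts adjusted over the list alone were also 9 and 10 (median log2 difference -0.07, camera adjusted p = 0.908). MYO7A was 1.72-fold higher in the utricle (adjusted p = 0.00709). OTOF, the otoferlin gene of ribbon synapses, was 2.23-fold higher in the utricle (adjusted p = 0.0259, range over the alternatives 9.87e-04 to 0.124), a call lost without utricle array 3 (0.0629) or utricle array 4 (0.0678). The transduction channel gene TMC2 was 1.65-fold higher in the cochlea (adjusted p = 0.043, or 0.0501 with replicate numbers as a block, range over the alternatives 0.0164 to 0.149). Its call was also lost, at adjusted p from 0.0512 to 0.107, without utricle array 2 or 3 or any cochlea array, and its log2 difference was -0.47 without utricle array 2.

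Genes of stereocilia and mechanotransduction also split. CIB3, a partner of the transduction channel, was at least 30.4-fold higher in the utricle. MYO1H was 16.9-fold and the actin-severing protein GSN 15.6-fold higher in the cochlea, where GSN was the brightest probe set on arrays 1 and 3, so signal saturation was not ruled out and would make that fold too small. Of 33 tested, 10 were higher in the utricle, 15 in the cochlea and 8 did not pass, with 10 and 15 adjusted over the list alone (median -0.11, camera adjusted p = 0.908). Among potassium and calcium channels and calcium handling genes, KCNA2 was at least 12.5-fold higher in the utricle, and KCNH7 6.18-fold and the calcium pump ATP2B2 3.47-fold higher in the cochlea. The counts for that list of 16 were 7, 5 and 4, with 8 and 5 adjusted over the list alone (median 0.27, camera adjusted p = 0.723). KCNMA1, the large-conductance calcium-activated potassium channel, had a log2 difference of -0.30 (adjusted p = 0.0971, range over the alternatives 0.0356 to 0.483). It passed with replicate numbers as a block (adjusted p = 0.0409) and without cochlea array 3 (0.0356).

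Synaptic genes included CABP1, 3.79-fold higher in the utricle, and SNAP91, 1.97-fold higher. The nicotinic receptor subunits CHRNA7 and CHRNA10 were higher in the cochlea, CHRNA7 at least 10.9-fold and CHRNA10 2.68-fold, and DNM1 was 1.88-fold higher. The subunit CHRNA9, which the naming rule does not take, was higher in the utricle (limma adjusted p = 3.69e-04). Of 18 ribbon and efferent synapse genes, 9 were higher in the utricle, 5 in the cochlea and 4 did not pass, and 9 and 5 passed adjusted over the list alone (median 0.54, camera adjusted p = 0.578).

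Supporting cell genes with the clearest differences were LFNG, a modifier of Notch receptors, 4.53-fold higher in the utricle, and SLC1A3, a glutamate transporter, 1.75-fold higher there. TIMP3, an inhibitor of matrix proteases, was 56.6-fold and the endocytic receptor LRP2 at least 59.7-fold higher in the cochlea. Of 22 tested, 7 were higher in the utricle, 8 in the cochlea and 7 did not pass, with 7 and 8 adjusted over the list alone (median -0.15, camera adjusted p = 0.908). Gap junction genes had 4 tested members, too few for camera, of which PANX1 was 2.68-fold higher in the utricle, GJA1 2.78-fold higher in the cochlea and 2 did not pass. Adjusted over the list alone, the counts were again 1 and 1 (median -0.33).

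The tectorins, structural proteins of the tectorial membrane, were bright in both tissues. TECTA was 3.66-fold higher in the cochlea (11.38 ± 0.79 against 9.50 ± 0.38), and TECTB 1.40-fold (15.30 ± 0.076 against 14.82 ± 0.070). On the cochlea arrays 14 to 21 probe sets were brighter than TECTB, so signal saturation was not ruled out and would make its fold too small. On the otolithic side, OTOL1 and OTOP1, the otopetrin proton channel, were higher in the utricle, OTOP1 by 33.5-fold, and SPARC was 1.74-fold higher there. SLC26A4, an anion exchanger, was at least 1.99-fold higher in the utricle. COL9A3 was 5.65-fold and SPP1 at least 12.3-fold higher in the cochlea. OC90, a protein of otoconia, had a log2 difference of 0.20 (adjusted p = 0.813, range over the alternatives 0.278 to 1) with an SD of 1.08 in each tissue, and without single arrays the difference ran from -0.33 without cochlea array 1 to 0.73 without utricle array 4. The 17 tectorial and otolithic genes gave 6 higher in the utricle, 8 in the cochlea and 3 not passing, with 6 and 9 adjusted over the list alone (median -0.48, camera adjusted p = 0.908).

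Among otic transcription factors, PAX2 was 26.0-fold higher in the utricle (10.09 ± 0.28 against 5.39 ± 0.34), IRX2 8.72-fold and SOX2 2.47-fold. HMX3 was at least 2.57-fold higher in the utricle (adjusted p = 0.0145, range over the alternatives 3.49e-05 to 0.116) but dim, at 5.46 ± 0.88 against 4.09 ± 0.072. Its call was lost without a filter (0.0593) and, in settings added later, without the arrays numbered 2 (0.0755) and without the 2 utricle arrays with high CALB1 (0.116, log2 difference 0.77). NR2F2 and RORB were higher in the cochlea, as given above. Of 21 tested, 9 were higher in the utricle, 7 in the cochlea and 5 did not pass, with 9 and 7 adjusted over the list alone (median 0.07, camera adjusted p = 0.908). GATA2 was named on the sheet but did not pass the filter, and no probe set was named GATA3, OTOGL or OCM.

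In the Notch pathway, the ligand DLL1 was 9.56-fold and HES6 at least 9.43-fold higher in the utricle, while HEY1 was 1.57-fold higher in the cochlea. Of 12 tested, 7 were higher in the utricle, 2 in the cochlea and 3 did not pass, with 7 and 2 adjusted over the list alone (median 0.57, camera adjusted p = 0.144). In the Wnt list, RSPO3 and PRICKLE2, the latter 14.8-fold, were higher in the utricle, and the secreted antagonists SFRP1 and SFRP2 were 5.80-fold and 5.57-fold higher in the cochlea. Other antagonists went both ways, FRZB and DKK3 being higher in the utricle and WIF1 in the cochlea (limma adjusted p = 7.78e-07, 4.66e-05 and 9.51e-05). The 26 tested Wnt genes gave 14, 9 and 3, with 14 and 9 adjusted over the list alone (median 0.40, camera adjusted p = 0.578).

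BMP ligands differed in opposite directions. BMP2 was 56.0-fold higher in the utricle (10.67 ± 0.20 against 4.86 ± 0.39), whereas BMP6 was at least 18.6-fold and BMP7 9.39-fold higher in the cochlea. ID1, a target of BMP signalling, was 12.5-fold higher in the cochlea, and LTBP1 7.44-fold higher in the utricle. CHRDL1, a BMP antagonist, was 1.47-fold higher in the utricle (adjusted p = 0.0484, range over the alternatives 0.0297 to 0.273). That call was lost, at adjusted p from 0.068 to 0.119, without any of utricle arrays 1, 2 and 3 or cochlea arrays 2, 3 and 4, and the log2 difference was 0.36 without cochlea array 2. Of 29 BMP and TGF-beta genes, 13 were higher in the utricle, 12 in the cochlea and 4 did not pass, with 14 and 12 adjusted over the list alone (median 0.30, camera adjusted p = 0.908).

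The FGF ligands FGF20 and FGF19 were at least 13.7-fold and 4.74-fold higher in the utricle, and FGF18 was at least 8.95-fold and the receptor FGFRL1 4.38-fold higher in the cochlea. The 17 FGF genes gave 5, 6 and 6, with 5 and 6 adjusted over the list alone (median -0.11, camera adjusted p = 0.908). In the hedgehog list, HHIP, which binds hedgehog ligands, was at least 36.4-fold higher in the utricle. GLI3 was 2.02-fold higher in the cochlea by its brighter probe set, but its other probe set was higher in the utricle, and the mean over both gave a log2 difference of 0.71. The 7 hedgehog genes gave 1, 1 and 5, with 1 and 1 adjusted over the list alone (median -0.12, camera adjusted p = 0.908). Among retinoic acid genes, ALDH1A3, which makes retinoic acid, was 14.8-fold higher in the utricle beside CRABP1, while the receptor RXRA was 3.04-fold and RBP5 1.94-fold higher in the cochlea. The 12 tested gave 5, 5 and 2, with 5 and 5 adjusted over the list alone (median 0.23, camera adjusted p = 0.578).

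Of 32 angiogenesis genes, 16 were higher in the utricle, 11 in the cochlea and 5 did not pass, with 16 and 11 adjusted over the list alone (median 0.23, camera adjusted p = 0.723). NRP1 was at least 5.62-fold and the chemokine CXCL12 6.32-fold higher in the utricle, and THBS2, an inhibitor of angiogenesis, at least 39.8-fold higher in the cochlea. The deposited workbook has an angiogenesis sheet of 36 genes chosen on these samples, which holds 6 of those 32, 5 of the 26 Wnt genes, 5 of the 12 retinoic acid genes, 4 of the 31 axon guidance genes and 2 of the 17 FGF genes, so these counts are not fully independent of that choice. Axon guidance genes included SEMA6D, 3.53-fold higher in the utricle, and EFNB1 and SLIT2, 6.39-fold and 2.82-fold higher in the cochlea. The 31 tested gave 14, 7 and 10, with 14 and 8 adjusted over the list alone (median 0.20, camera adjusted p = 0.578).

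Motile cilia genes were the list with the largest shift. TEKT1, a filament protein of axonemes, was 15.9-fold higher in the utricle (9.36 ± 0.10 against 5.36 ± 0.084), and RSPH1, a radial spoke protein, 14.4-fold. CCDC40, an axoneme assembly factor, was 5.94-fold higher in the cochlea and CAPSL at least 1.93-fold. Of 22 tested, 20 were higher in the utricle and 2 in the cochlea, also when adjusted over the list alone (median 2.04, camera adjusted p = 3.87e-07). With an estimated correlation the adjusted p was 0.408. The median was 1.96 with tissue means under 4 raised to 4.

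Cell cycle genes were higher in the utricle in 14 of 24, higher in the cochlea in 4, and 6 did not pass, with 15 and 4 adjusted over the list alone (median 0.63, camera adjusted p = 0.0487). The adjusted p of the list was 0.744 with an estimated correlation and 0.0578 with replicate numbers as a block. CDCA3, a mitotic regulator, was at least 9.05-fold, the condensin subunit SMC2 at least 2.02-fold and the topoisomerase TOP2A 2.03-fold higher in the utricle. The cyclin CCND2 was 3.04-fold and the checkpoint protein MAD2L1 1.65-fold higher in the cochlea.

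Immediate early and heat shock genes, which respond to handling of tissue, passed in 5 of 16, with BTG1 2.02-fold higher in the utricle and KLF6 and MYC 2.87-fold and 1.98-fold higher in the cochlea. The counts were 2, 3 and 11, with 2 and 2 adjusted over the list alone (median 0.29, camera adjusted p = 0.947). Cytosolic ribosomal proteins differed little, RPL9 being 1.25-fold and RPL12 1.32-fold higher in the utricle, and RPS13 1.20-fold higher in the cochlea. In a setting added later, without the 2 utricle arrays with high CALB1, RPL12 (adjusted p = 0.0573) and RPS13 (0.0522) lost their calls. Of 56 tested, 10 were higher in the utricle, 3 in the cochlea and 43 did not pass, and 0 and 0 passed adjusted over the list alone (median 0.08, camera adjusted p = 0.329). Of 52 oxidative phosphorylation genes, 5 were higher in the utricle, 10 in the cochlea and 37 did not pass, with 5 and 10 adjusted over the list alone (median -0.08, camera adjusted p = 0.578). COX6C was 1.71-fold higher in the utricle, and UQCRB and NDUFB4 were 2.34-fold and 1.87-fold higher in the cochlea.

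**Figure D2:**
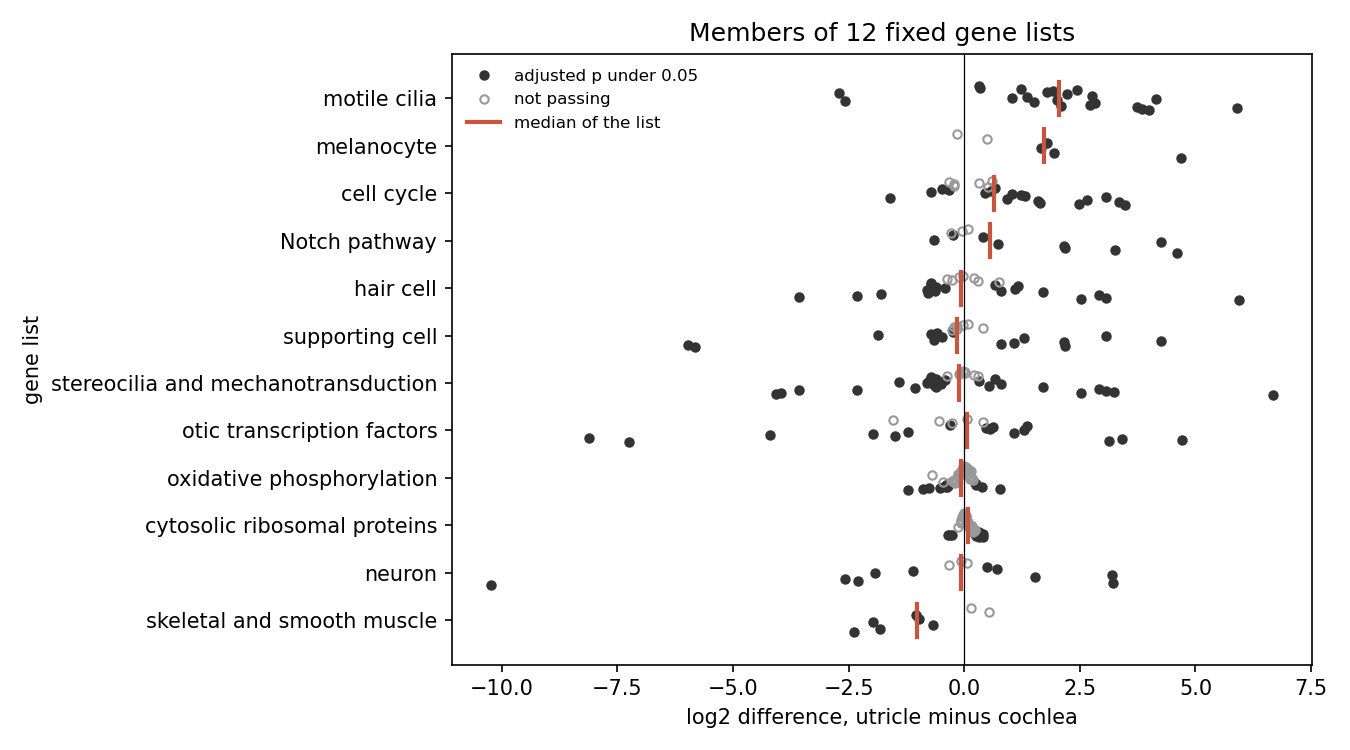
Log2 differences, utricle minus cochlea, of the tested members of 12 gene lists (filled points pass at an adjusted p under 0.05, open points do not), with the median of each list as a red bar. The motile cilia median lies at 2.04 and the hair cell median at -0.07.

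Tested markers of other cell types moved in both directions. Many listed symbols were not tested. Those tested were 6 of 14 for melanocytes, 8 of 28 for muscle and 5 of 36 for leukocytes. For endothelium, erythrocytes and fibroblasts they were 4 of 22, 7 of 27 and 11 of 30. For cartilage and bone, neurons and dark cells they were 10 of 24, 13 of 28 and 6 of 21. The counts below do not show that a cell type was present. Melanocyte markers were higher in the utricle in 4 of 6 and 2 did not pass, with 4 and 0 adjusted over the list alone (median 1.73, camera adjusted p = 0.0487). With an estimated correlation the adjusted p of that list was 0.41, and with replicate numbers as a block 0.115. OCA2, a melanosome protein, was at least 7.92-fold and the receptor KIT 3.83-fold higher in the utricle. The median was 1.12 with tissue means under 4 raised to 4. Muscle genes were higher in the cochlea in 6 of 8 and in the utricle in 0, also adjusted over the list alone, with TNNC1 5.23-fold and ACTA1 3.52-fold higher (median -1.01, camera adjusted p = 0.144). Of 5 leukocyte genes, 4 were higher in the utricle, among them CD74 at 3.08-fold, and 1 in the cochlea, also adjusted over the list alone (median 1.41, camera adjusted p = 0.299).

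Among 4 endothelial genes, 2 were higher in the utricle, LYVE1 at least 10.2-fold, and 2 in the cochlea, CLDN5 at least 8.86-fold, with the same counts adjusted over the list alone (median -0.48, too few for camera). Erythrocyte genes gave 0 higher in the utricle, 1 in the cochlea, CA2 at 24.3-fold (13.5-fold without utricle array 1 and 38.3-fold without utricle array 4), and 6 not passing, with 0 and 1 adjusted over the list alone (median 0.04, camera adjusted p = 0.908). The 11 fibroblast and mesenchyme genes gave 5, 3 and 3, with 5 and 3 adjusted over the list alone (median 0.65, camera adjusted p = 0.908), with ELN at least 2.07-fold higher in the utricle and COL14A1 4.07-fold in the cochlea. The 10 cartilage and bone genes gave 3, 5 and 2, with 3 and 5 adjusted over the list alone (median -0.41, camera adjusted p = 0.723), with ACAN at least 5.39-fold higher in the utricle and LECT1 and HAPLN1 37.0-fold and 19.9-fold in the cochlea. Neuronal genes gave 5, 5 and 3 of 13, with 5 and 5 adjusted over the list alone (median -0.07, camera adjusted p = 0.908), with RTN1 9.27-fold higher in the utricle and NEFM and UCHL1 higher in the cochlea, UCHL1 by 4.93-fold. The 6 dark cell genes gave 1, 1 and 4, with 1 and 1 adjusted over the list alone (median 0.22, camera adjusted p = 0.908), SLC26A4 in the utricle and ATP1B1, 2.26-fold, in the cochlea.

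Over the 29 lists tested, camera called 3 (motile cilia, cell cycle and melanocyte), and 0 with an estimated correlation. The count was 1 with replicate numbers as a block, and 1 without utricle array 2 and without utricle array 3. The median, the mean and the camera test of a list did not share a sign for hair cells, stereocilia, tectorial and otolithic membranes, otic transcription factors, BMP and TGF-beta, hedgehog, angiogenesis and erythrocytes. The direction by fry, which weighs a list's own genes without comparing them with others, was opposite to camera for stereocilia, tectorial and otolithic membranes, otic transcription factors, BMP and TGF-beta, FGF, hedgehog and fibroblasts.

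The authors' deposited table, made with SAM, calls 3496 probe sets higher in the utricle and 3210 higher in the cochlea, all at a fold of at least 1.5 and a q-value of at most 2.93%. Of the 3115 utricle calls of the authors' deposited table among the probe sets tested here, 3000 (96.3%) were also called higher in the utricle by limma, where 823 would be shared if the calls were independent. Of its 2885 cochlea calls there, 2829 (98.1%) were shared, against 723.1. For 0 calls of the authors' deposited table did limma call the opposite direction. Both comparisons used the same arrays and are not independent evidence.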

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

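Of the tests below, the prefix, hair cell share and carry-over tests and the 7 split counts of probe sets, genes and lists were chosen after the results they concern had been seen, and so was the minimum of 3 tested pigment genes. Single arrays stood apart from the other 3 of their tissue in 11 of 232 groups of values of the named genes, where chance gives about 11.6, or 1 in 20. Toward a higher value these were GSTTL on cochlea array 4 (13.513 against 13.323 to 13.337), DLL1 on utricle array 2 (11.553 against 11.215 to 11.265), HEY1 on utricle array 2 (12.065 against 11.722 to 11.78), PRICKLE2 on cochlea array 3 (4.586 against 4.214 to 4.266), DNAJB6 on utricle array 2 (11.371 against 10.814 to 10.889) and ACTA1 on cochlea array 4 (9.156 against 8.467 to 8.569). Toward a lower value these were SNAP91 on utricle array 2 (13.709 against 13.849 to 13.852), CHRNA7 on cochlea array 2 (7.001 against 7.558 to 7.648), HES6 on utricle array 4 (6.893 against 7.329 to 7.374), HAPLN1 on utricle array 2 (7.278 against 7.558 to 7.573) and OC90 on utricle array 4 (12.052 against 14.124 to 14.265).

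Among the 35 distinct splits of the 8 arrays into 4 and 4, the split by tissue was the only 1 of 35 with as many probe sets called toward either tissue (4286 and 4066, with 0 as the highest of the other splits), with at least a 2-fold difference (1811 and 1630, other splits 0) and with as many genes (2320 and 2311, other splits 1). Chance can be excluded for those 6 counts only over free splits, which set the pairing of equally numbered arrays aside. For the number of lists called by camera it could not be: 16 of 35 splits gave 3 or more, and the highest other gave 7. Of the 8 splits that part all 4 pairs of equally numbered arrays, the highest other gave 4 lists and 0 genes, and the 27 splits that keep some pair together gave up to 7 lists and 1 gene. The 8 splits alone are too few to exclude chance, so under the pairing it was not excluded.

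The median of the motile cilia list was largest under the tissue split, in 1 of 35 splits, at 2.045 against 1.154 at most. For this 1 list, chance can be excluded as the source of a tissue difference only over free splits, which set the pairing aside. That holds without allowance for the 29 lists tested. The splits cannot say whether the list shifted more than other genes, of which many differed, with 4631 of 8514 called. Camera, which compares a list with other genes, called it with the preset correlation (adjusted p = 3.87e-07) but not with an estimated one (0.408). The 8 splits that part all pairs taken alone are too few to exclude chance, with 1.154 as the highest other. Within the 6 arrays of the larger prefix the median was 2.071. Each prefix held as many utricle as cochlea arrays, so a shift shared by the arrays of a prefix cancels in the tissue difference. That value is therefore no further test of the prefix. A shift of the 1 utricle array set apart by the number after the prefix would not cancel. Camera with the preset correlation still called the motile cilia list without each array in turn. The hair cell list had a median of -0.072, which lies 2.117 below the motile cilia median. This met the condition set against a larger share of hair cells in the utricle samples. However, the hair cell genes moved in both directions, 9 higher in the utricle and 10 in the cochlea, with an SD of 1.889 over members. Their median therefore does not measure the share of hair cells, and a larger share stays open. A difference between the tissues in the cells themselves also stays open and was not tested.

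CALB1 was 2.489, 7.467, 6.891 and 2.498 on utricle arrays 1 to 4. The 3 of the larger prefix alone spanned 4.969 on the log2 scale, or 3.467 with values under 4 raised to 4. That span argues against the prefix itself as the source. It does not test the number after the prefix, which set 1 of those 3 arrays apart, so that number stays open. Carry-over of cochlear RNA could not be decided: the CALB1 level of array 2 would need 0.418% of cochlear RNA, and 33.3% of the 6 other genes at least 6 (log2) higher in the cochlea, with a mean of at least 12 there, lay more than 1 below what that predicts. The genes that far below it were NEFM (2.568 against 4.927) and GSTTL (3.585 against 5.476), both under 4 on that array. The rule did not count genes above the prediction, as were ATOH8 (6.772 against 4.141) and CRISP3 (8.712 against 5.413). NR2F2 (7.073 against 6.252) and SLC34A2 (4.273 against 4.895) lay closer to it. The spread was not particular to CALB1, since the 3 of those 6 with their 2 highest utricle values above 4 (ATOH8, CRISP3 and NR2F2) had these on the same 2 arrays, as did 16.2% of 3337 other genes with a utricle mean under 8. For carry-over in both directions between the arrays numbered 2, a wider cut was used, a mean of at least 10 without genes whose spread had been seen before, and 6 of 9 genes at least 6 higher in the utricle and 7 of 12 in the cochlea had their highest value in the other tissue on array 2, the smaller share being 58.3%, between the bounds set for and against it. In 2 of those 9 and 3 of those 12 that highest value was under 4, where its rank says little, and no biological explanation was tested.

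The melanocyte list had a median of 1.725 under the tissue split against 0.942 at most under the others, in 1 of 35 splits. For this 1 list, chance can be excluded as the source of a tissue difference only over free splits, with the same limits as for motile cilia. The 8 splits that part all pairs taken alone are too few to exclude chance (0.932 as the highest other). Camera did not call the list with an estimated correlation (adjusted p = 0.41) or with replicate numbers as a block (0.115), and the median was 1.12 with means under 4 raised to 4. Melanocytes in the utricle samples are a candidate source, and the condition set in advance, that at least 50% of the tested pigment genes pass as higher in the utricle, was met by DCT alone, the 1 that was tested, with no value above 5.002. TYR, PMEL and MLANA stayed at the floor of 2.222 on every array and TYRP1 reached at most 5.216, so a minimum of 3 tested genes, added afterwards, leaves the source open. KIT was bright in both tissues, at 12.06 and 10.12, and SOX10, a marker also on another list that was picked after its value was seen, had a log2 difference of -0.16 (adjusted p = 0.19).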

How the results depend on the processing

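The ranges here include the 4 alternatives added after the data were seen. The counts of probe sets and genes stayed within 1.5 times their reported values under every alternative run: genes higher in the utricle 1953 to 2596, genes higher in the cochlea 1899 to 2568, and between 4203 and 5935 calls shared with the authors' deposited comparison. Without single arrays they were 2039 to 2268, 2020 to 2157 and 5535 to 5768. The median log2 difference over all genes was 0.005, and -0.043 with equal array medians. Of the 4631 genes called, 3698 to 4631 kept their call and direction under the alternatives with a count of shared genes, and 0 were called the opposite way. The lowest gene counts, 1953, 1899 and 3698, came from an alternative added later, without the 2 utricle arrays with high CALB1.

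The number of lists called, 3, was 1 with a filter at 6, with trend and robust, with array weights, with the replicate block, and, added later, with the prefix block, without the arrays numbered 2 and without the 2 utricle arrays with high CALB1. It was 0 with an estimated correlation, 17 with fry, and 1 to 3 without single arrays. Motile cilia kept its call except with an estimated correlation, and without a filter the ribosomal list passed (adjusted p = 0.021, elsewhere up to 0.978). With the replicate block, genes higher in the utricle were 2596 and in the cochlea 2568. The pairing ended the calls of the cell cycle (adjusted p = 0.0578) and melanocyte lists (0.115) and of TMC2 (0.0501), added KCNMA1 (0.0409), and changed no other call of a named gene or list.

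Of 133 named genes, 131 passed, 117 of them under all 22 alternatives with a value. The other 14 lost the call under at least 1, and KCNMA1 gained it. Those 14 include PECAM1, EGFL7, LY86, DNER, COL6A3 and RPS15, which are counted in their lists but not named above. The endothelial genes PECAM1 and EGFL7 reached a limma adjusted p of 0.168 and 0.0508. LY86, the leukocyte gene higher in the cochlea, reached 0.0682. GLI3 reversed to 0.707 (adjusted p = 0.0057) with the mean over its probe sets, which differ in direction. For DNAJB6, with probe sets that also differ, that mean gave 0.001. Fewer arrays or more genes tested account for part of these losses by construction, and otherwise the cause was not tested. The SAM-style test gave no list test, the mean over probe sets no count of probe sets, and genes under a stricter filter no value there. Signal over background limits folds for genes under 4 in a tissue to lower bounds.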
